A study of Mus musculus with 3 samples.

How the data were processed

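Single cells from enzymatically dissociated mouse bladder and bladder assembloids had been captured with the 10x Genomics Chromium Single Cell 3′ kit, version 3, from polyA RNA. Each of the 3 groups (adult bladder, 1-day assembloids and 7-day assembloids) had 1 library, made from a pool of 8 bladders or of 3 assembloids. The deposited matrices hold UMI counts per gene and barcode, whole numbers with no normalization. The submitters' processing notes name Cell Ranger and the builds GRCh38, mm10 and hg38, and per the file headers the version was 3.1.0. The feature IDs carry a prefix for human GRCh38 or mouse mm10 genes, so reads had been assigned to a combined gene set. The annotation release and the settings by which the submitters called cells are not given in the sources used here. Gene positions were taken from GENCODE vM21, which uses mm10, for 475 of 475 gene IDs looked up.

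A barcode with at least 90% of its UMIs on mouse genes was taken as a mouse cell and one with at least 90% on human genes as a human cell. The bladder, 1-day and 7-day libraries held 8338, 8899 and 9059 mouse barcodes, 147, 115 and 138 human barcodes and 157, 25 and 351 mixed ones, which were left out. Mouse cells were kept with at least 500 genes, under 20% mitochondrial UMIs and no doublet call by Scrublet, run per library with the default settings of scanpy 1.11.5. This left out 1108, 241 and 514 mouse barcodes for few genes, 217, 120 and 171 for mitochondrial UMIs, and 226, 279 and 201 as doublets (3.22%, 3.27% and 2.40%). Kept cells had a median of 2491, 3704 and 2627 genes and of 5.33%, 4.87% and 4.92% mitochondrial UMIs. The bladder library's human barcodes held at most 1 UMI each and none was kept.

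The kept mouse cells of all 3 libraries were clustered together without batch integration, by Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1) on a shared-neighbour graph of 15 neighbours over 30 principal components of 2000 variable genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9. A marker counted for a cluster where at least 25% of its cells had a UMI of it and its CPM, with an offset of 5, was at least 2-fold that in all other cells. The candidate class had at least 3 counted markers and the highest share of its list counted. The name was kept where the 10 genes with the highest fold held at least 1 marker of that class and no more of any other. The marker lists, the gene lists and the rule for named genes, together with the filters, the main settings and most alternatives below, were chosen before the data were examined. The cells used as reference for the 10 highest genes were chosen afterwards. All other cells were planned, which left cluster 9 without a name, and cells of other candidate classes were then used. Cluster 9 had 13 urothelial markers at least 2-fold over all other cells, and its 10 highest genes against all other cells held 1 pericyte marker, Ndufa4l2, and 0 urothelial ones. Clusters 3, 6, 8, 10 and 34 took no name.

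The UMI counts of the cells of a class were summed per library and scaled to CPM, the share of a gene in all mouse UMIs of the class, and log2 ratios were computed with 0.5 counts added to each sum. Because 1 library per group leaves no degrees of freedom, no test was run, and no p-value, standard error or count of changed genes over the transcriptome is given. Cells are not replicates of a library. The exact intervals of ratios and the Clopper-Pearson intervals of shares cover counting error only. A list member was measured with at least 20 CPM in the higher library and counted as higher or lower with a ratio of at least 2-fold whose interval excluded 1. Medians of lists carry intervals from 1000 Poisson draws and a percentile among 10000 random lists matched on mean expression. Where a gene was at 0 UMIs, the fold is given against a floor of 3 counts over the class.

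The 21 gene lists covered umbrella cell genes, basal urothelial genes, keratinization, tight junctions, urothelial transcription factors, G2/M, S phase, immediate early genes, hypoxia and glycolysis, hedgehog, Wnt and BMP signalling, fibrillar matrix, matrix remodelling, contractile genes, inflammatory cytokines, interferon response, cholesterol synthesis, oxidative stress, oxidative phosphorylation and antigen presentation. Named genes were, for each comparison within a main class, the 6 highest and 6 lowest log2 ratios among genes with at least 100 CPM in the higher library, and up to 4 members of each list by absolute log2 ratio with at least 20 CPM. Mitochondrial, ribosomal protein, hemoglobin, sex-linked and predicted genes, Malat1 and Neat1 were not named, nor were genes whose CPM over the other cells was over 5 times that in the class. A few genes that met the rule were withheld and are left out. Other genes, among them Shh, Krt5 and those of the plots, come from the lists or from the set fixed for shares of cells with a UMI. Urothelial-like and fibroblast-like cells were the main classes. Other classes with at least 50 cells in each of 2 libraries were described by their lists and leading genes.

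For shares of cells with a UMI, each cell was thinned to 2500 UMIs, the 10th percentile of the shallowest library rounded down. This left out 652, 268 and 1575 shallower cells of the bladder, 1-day and 7-day libraries. The split of the 7-day cells by their 30 nearest cells of the other libraries, with limits of 5% and 95%, was made after the data were seen. For free RNA, the 30 genes highest in 1 library among those under 2 CPM in the other were summed. Human cells were kept with the same limits and described apart.

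The functions were tested on simulated data for the urothelial-like comparison of 1-day assembloids with bladder (4938 genes) and the fibroblast-like comparison of 7-day with 1-day assembloids (5356 genes). In each, 100 of 100 genes simulated at 3-fold and 0 of 100 at 1.5-fold met the rule for higher or lower, as did 0 of 4738 and 0 of 5157 unchanged genes. The 95% intervals held the simulated ratio for 94.9% and 95.0% of genes. A list shifted by 1 on the log2 scale gave a median of 1.00 in both, and 7.5% and 7% of 200 unshifted lists fell outside the middle 95% of random lists. The simulated counts held counting error only. They had no variation between libraries, pools or cells, so these rates do not describe errors from such variation in the real data.

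The alternatives tried were a looser cell filter (200 genes, no mitochondrial limit), a stricter one (1000 genes, under 10%), Scrublet calls kept, resolutions 0.5 and 2, the class by most marker UMIs, per-cell CPM averaged, median-of-ratios scaling, no minimum and a minimum of 100 CPM for list members, cells thinned before summing, no thinning of shares, and a purity of 80%. Added after the data were seen were the urothelial-like class without cluster 9, the 7-day library without bladder-side cells, and 1-day fibroblast-like cells with a Y-linked transcript and no Xist. Median-of-ratios scaling moved all log2 ratios by 0.17 (7-day over 1-day), −0.01 (7-day over bladder) and −0.16 (1-day over bladder) in urothelial-like cells, and by 0.01, −0.13 and −0.17 in fibroblast-like cells.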

Results

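Single-cell transcriptomes were measured in 3 libraries of dissociated mouse bladder tissue, 1 library for each of 3 groups, so there were no replicates and no test between groups was possible. The first group was adult bladder from C57BL/6 mice aged 8 to 9 weeks, pooled from 8 bladders. The other groups were bladder assembloids, constructs in which organoid epithelium is rebuilt with stromal cells in culture, pooled from 3 assembloids after 1 day and from 3 assembloids after 7 days. The deposited matrices held 8642, 9039 and 9548 barcodes in the bladder, 1-day and 7-day libraries, with 93560608, 135955678 and 120301672 UMIs in total. After filtering, 6787, 8259 and 8173 mouse cells remained, with a median of 7529, 14940.0 and 9390.0 UMIs per cell. Intervals given below in brackets are 95% intervals (Clopper-Pearson for shares, exact Poisson for ratios) and cover counting error only. The limit given for a count of 0 is not an interval but the share that 3 counts of the total would make. Cells of 1 library share its pool and its handling, which the intervals leave out.

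The labels set adult bladder beside assembloids of both ages, which asks which bladder cell types and expression programmes an assembloid holds and how they differ between 1 and 7 days. Clusters were assigned to urothelial-like, fibroblast-like, smooth muscle-like, pericyte-like, endothelial-like, glia-like, mesothelial-like, myeloid and lymphocyte classes by marker genes. Urothelial-like cells, the epithelium that lines the bladder lumen, made up 39.6% [38.4 to 40.8] of mouse cells in bladder (2688 cells), 17.7% [16.9 to 18.6] at 1 day (1463 cells) and 26.0% [25 to 26.9] at 7 days (2121 cells). In bladder almost all lay in clusters 0, 5, 13 and 35, at 1 day in clusters 7, 9 and 33, and at 7 days in clusters 0, 5, 13, 35, 7, 9 and 33. Cluster 9 held 702 cells at 1 day, 310 at 7 days and 0 in bladder, and its place among the urothelial-like cells depended on the cells it was compared with. With cluster 9 left out of the class, the urothelial-like share was 9.21% at 1 day and 22.2% at 7 days. Fibroblast-like cells made up 21.5%, 24.8% and 27.0% of cells in bladder, 1-day and 7-day libraries (1459, 2050 and 2208 cells). Almost all lay in clusters 2, 22 and 24 in bladder, in clusters 1, 4 and 23 at 1 day, and in all of these at 7 days. Endothelial-like cells made up 16.8%, 5.44% and 12.2%, smooth muscle-like cells 9.11%, 3.27% and 6.41%, and pericyte-like cells 6.48%, 0.581% and 4.18%. Glia-like cells made up 4.23%, 8.32% and 2.36%, mesothelial-like cells 0.766%, 2.45% and 0.502%, and myeloid cells 0.899%, 1.03% and 1.03%. Lymphocytes were 0.545% of bladder cells and 0.159% of 7-day cells, and 0 of 8259 cells at 1 day, which at 3 counts allows a share of up to 0.0363%. Cells of clusters that took no class name made up 0.0884%, 36.4% and 20.2%. Among these, cluster 3 (902 cells at 1 day and 518 at 7 days) had smooth muscle as its candidate class. It took no name because none of its 10 highest genes was a smooth muscle marker, so the smooth muscle-like shares of assembloids may leave such cells out. These shares describe the cells that were dissociated, captured and kept.

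**Figure D1:**
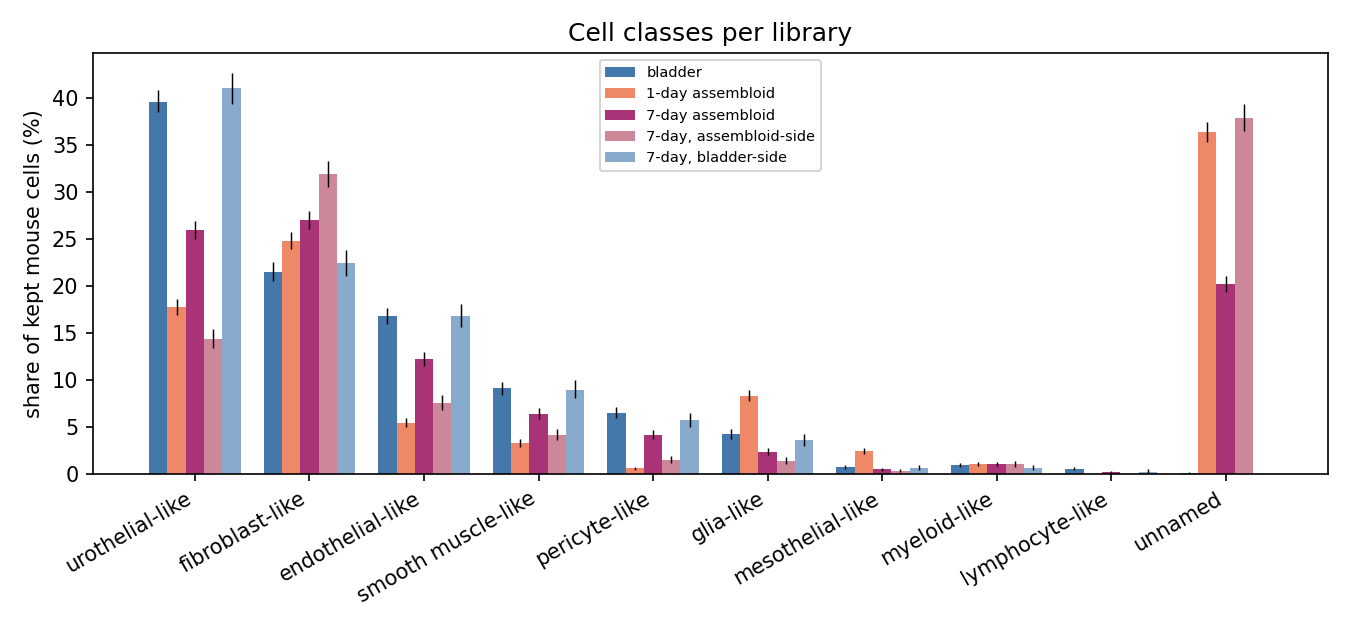
Share of kept mouse cells (%, y axis) in each cell class (x axis) for the bladder, 1-day and 7-day libraries, with Clopper-Pearson 95% intervals as error bars. The urothelial-like share was 39.6% in bladder, 17.7% at 1 day and 26.0% at 7 days.

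The 7-day library held cells of both kinds of profile seen in the other libraries. For each 7-day cell, the 30 nearest cells of the bladder and 1-day libraries were counted. Among 8173 cells of the 7-day library, 4349 (53.2% [52.1 to 54.3]) had at most 5% bladder cells among these neighbours and are called assembloid-side cells, 3590 (43.9% [42.8 to 45.0]) had at least 95% and are called bladder-side cells, and 234 (2.86%) lay between. The bladder-side cells had a median of 3329 UMIs and the assembloid-side cells a median of 19917 UMIs. Bladder-side cells were 41.0% urothelial-like, 22.4% fibroblast-like, 16.8% endothelial-like, 8.97% smooth muscle-like and 5.71% pericyte-like, shares that lay close to those of the bladder library. No bladder-side cell was in an unnamed cluster, which at 3 counts allows a share of up to 0.0836%, against 37.9% of the assembloid-side cells. Assembloid-side cells were 14.4% urothelial-like and 31.9% fibroblast-like. Most class values of the 7-day library therefore mix both sides, and assembloid-side values are given beside many of them.

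**Figure D2:**
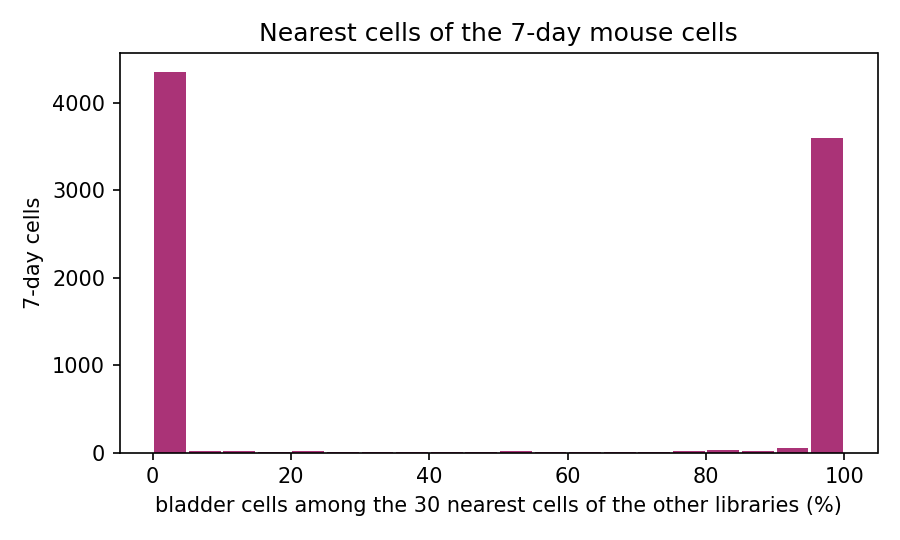
Number of 7-day cells (y axis) by the percentage of bladder cells among their 30 nearest cells of the other libraries (x axis, bins of 5 percentage points). The assembloid-side end holds 4349 cells and the bladder-side end 3590, with 234 cells between.

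The first comparison set 1-day assembloids against adult bladder within the urothelial-like cells, which asks how the epithelium differs from its adult state after 1 day of culture. In the umbrella cell list, named for the superficial cells that carry uroplakin plaques, Upk3a, Upk2, Upk1a and Krt20 were lower. Upk3a was not confined to umbrella cells here, since almost all bladder urothelial-like cells held it, as the shares below show. Upk3a and Upk1a were also leading genes of cluster 13, beside Krt5 and Krt15. The lower uroplakin levels therefore describe the whole class and are not read as a loss of umbrella cells. Upk3a (ENSMUSG00000022435, mm10 chromosome 15, 85017141 to 85022547, a protein-coding gene) fell from 5096 to 191 CPM, a log2 ratio of −4.74 [−4.81 to −4.66]. Without cluster 9, Upk3a stood at 58.0 CPM at 1 day, a log2 ratio of −6.45. Krt20 (ENSMUSG00000035775, chromosome 11, 99428403 to 99438150), a keratin of umbrella cells, fell from 63.9 CPM to 3 UMIs in the whole class, a log2 ratio of −7.19 [−9.69 to −5.87]. Upk2 fell from 627 to 87.1 CPM and Upk1a from 2917 to 1227 CPM, while Upk3bl and Gsdmc2 of the same list rose from 2.9 to 27.8 and from 31.5 to 234 CPM. Among the 10 measured umbrella cell genes, 3 were higher and 5 lower by at least 2-fold, and the median log2 ratio was −0.60 [−0.65 to −0.57], at the 0.29 percentile of 10000 random lists matched on expression. Cluster 9 carried part of this list, and the median without it was −1.57. Per-cell averages of CPM gave −0.69.

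Basal urothelial genes moved the other way, with a median log2 ratio of 1.20 over 11 measured genes, 6 of them higher and 0 lower. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548), a keratin of basal and injured epithelium, rose from 1.2 to 48.4 CPM, a log2 ratio of 5.32 [4.97 to 5.70]. Col17a1, a hemidesmosome collagen, rose from 0.9 to 42.5 CPM, Itgb4 from 28.6 to 86.3 CPM and Krt15 from 1295 to 3906 CPM. Squamous genes went both ways, with 3 of 6 measured genes higher and 3 lower. Krt13 rose from 2.2 to 31.8 CPM and Krt4 from 56.0 to 306 CPM, and the cornified envelope gene Ivl fell from 1955 to 687 CPM. The tight junction list had a median of −0.31 over 11 genes, a median that turned to 0.14 at a minimum level of 100 CPM, with Cldn3 higher (0.39 to 35.4 CPM) and Cldn8, Ocln and Cldn4 lower. Cldn4, the most abundant of these, fell from 1615 to 532 CPM. Of 14 urothelial transcription factors, Trp63 of basal cells rose from 66.7 to 156 CPM, and Grhl3, Ovol1 and Klf4 of differentiating cells fell, from 110, 120 and 256 CPM to 12, 21.6 and 91.1 CPM.

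All 17 measured hypoxia and glycolysis genes were higher at 1 day by at least 2-fold, with a median log2 ratio of 2.66 [2.63 to 2.72], above all 10000 random lists. The mitophagy gene Bnip3 (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519) rose from 13.3 to 272 CPM, a log2 ratio of 4.35 [4.24 to 4.47], the prolyl hydroxylase Egln3 from 14.4 to 301 CPM, and Pgk1 from 76.6 to 1020.4 CPM. Without cluster 9, Bnip3 stood at 144 CPM at 1 day, a log2 ratio of 3.44, and the hypoxia median was 2.34. Outside the urothelial-like cells, Pgk1 stood at 103 CPM in bladder and 519 CPM at 1 day. Oxidative stress genes were lower, with 7 of 13 measured genes lower, 0 higher and a median of −1.11. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) fell from 421 to 43.7 CPM, Gstm1 from 20772 to 2706 CPM, Nqo1 from 53.4 to 8.5 CPM and Gclc from 237 to 44.1 CPM. The cholesterol synthesis list had a median of −0.73 with 4 of 11 genes lower, among them Fdps (202 to 77.3 CPM). The antigen presentation list had a median of −0.98 over 6 genes, with B2m lower (263 to 44.6 CPM) and H2-Ab1 higher (0.3 to 20.4 CPM). Immediate early genes, which dissociation can induce, had a median of −0.65 over 15 genes, with Nr4a1 lower (217 to 57.7 CPM) and Ier2 higher (160 to 355 CPM).

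Of the G2/M genes only Ube2c and Top2a reached 20 CPM, and both were higher at 1 day, Ube2c from 0.3 to 32.7 CPM and Top2a from 2.1 to 24.8 CPM, a median log2 ratio of 5.10 [4.78 to 5.54]. The S phase list had a median of 0.14 over 4 genes, with Mcm7 higher (8.6 to 23.9 CPM). The epithelial ligand Shh was 105 CPM in bladder and 83.6 CPM at 1 day, a difference below 2-fold. Bmp2 fell from 110 to 10.0 CPM and Id3 rose from 78.3 to 277 CPM, within a BMP list whose median of −0.30 turned to 0.08 at a minimum level of 100 CPM. The Wnt list (3 genes, median −0.14) held no gene changed by 2-fold. The oxidative phosphorylation list, with a median of 0.13 over 14 genes, held none either. The interferon list had a median of 0.91 over 4 genes, with Ifi27 and Ifitm3 higher. Cxcl10 fell from 60.6 CPM to 2 UMIs, a log2 ratio of −7.60 [−10.97 to −6.07], and Il33 rose from 6.6 to 41.0 CPM. Mesenchymal transcripts were also higher in the 1-day urothelial-like cells, and here other cells held far more of them. Acta2 was 371 against 6.28 CPM in the class and 8406 against 2891 CPM in all other cells, and Timp1 was 93.6 against 0.094 CPM in the class and 3451 against 40.9 CPM in the others. Contractile, fibrillar matrix and remodelling lists in this class move with the level in the other cells of the library, and they are not read as expression.

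Genes with the largest differences in this comparison included several outside the lists. Ghrh (ENSMUSG00000027643, chromosome 2, 157329497 to 157347506), the growth hormone releasing hormone gene, was at 166 CPM at 1 day and at 0 UMIs in bladder, at least 3523-fold higher against a floor of 3 counts over the class. Ndufa4l2 rose from 0.33 to 564 CPM, Cd53 from 0.27 to 181 CPM, Ly6a from 8.18 to 1089 CPM, the prostaglandin E synthase Ptges from 5.51 to 308 CPM and Fxyd4 from 14.2 to 580.2 CPM. Ghrh, Ndufa4l2, Cd53 and Fxyd4 are among the leading genes of cluster 9, which held 702 of the 1463 cells at 1 day. Without it they stood at 6.61, 248, 168 and 216 CPM at 1 day, so the level of Ghrh in the class came mostly from that cluster, and Ly6a and Ptges stood at 1079.8 and 239 CPM. The prostaglandin-degrading enzyme Hpgd fell from 128 CPM to 1 UMI, a log2 ratio of −9.42 [−15.31 to −7.53]. Wfdc15b fell from 169.6 to 2.37 CPM, Nr4a3 from 104 to 1.62 CPM, Flrt3 from 181 to 3.12 CPM, Adh1 from 219.7 to 5.98 CPM and Uchl1 from 398 to 13.5 CPM.

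**Figure D3:**
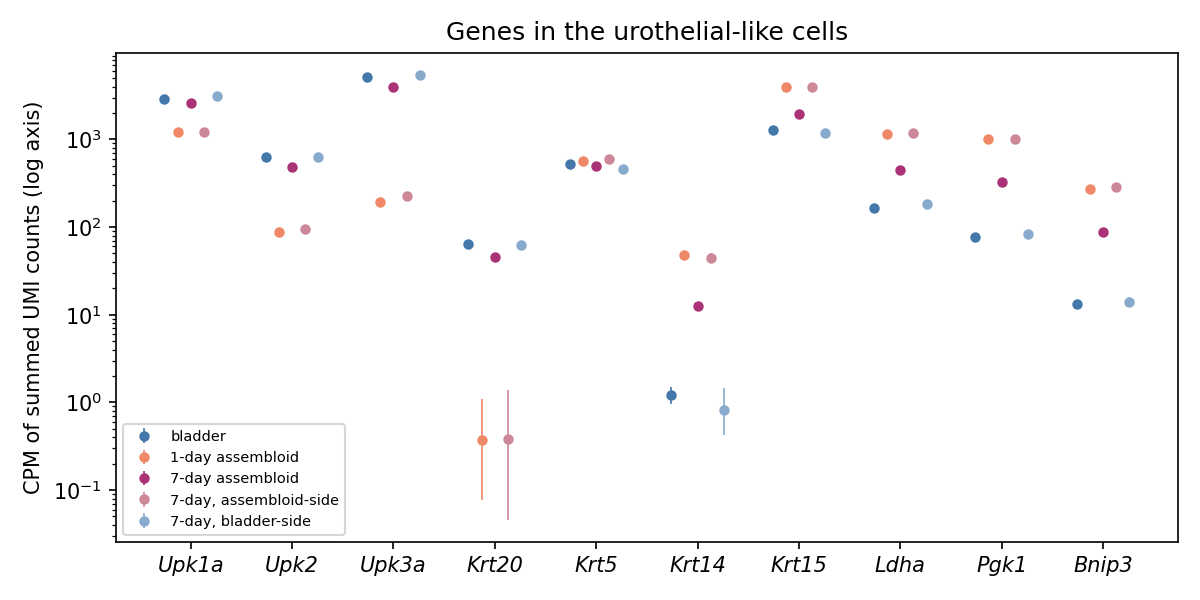
CPM of 10 genes in urothelial-like cells (log y axis) in bladder, 1-day and 7-day libraries and in the assembloid-side and bladder-side cells of the 7-day library, with exact Poisson 95% intervals, genes at 0 counts not drawn. Upk3a stood at 5096 CPM in bladder, 191 CPM at 1 day, 3971 CPM at 7 days and 228 CPM in the assembloid-side 7-day cells.

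The second comparison set 7-day against 1-day assembloids within the urothelial-like cells, which asks whether the epithelium changed between these ages. In the library as deposited, most hypoxia genes were lower at 7 days and some basal genes were. Umbrella cell genes went both ways, with Upk3a, Upk2, Upk1a and Krt20 among the higher ones. Upk3a rose from 191 to 3971 CPM, a log2 ratio of 4.38, Upk2 from 87.1 to 487 CPM and Upk1a from 1227 to 2620.5 CPM, and Krt20 rose from 3 UMIs to 46.1 CPM, a log2 ratio of 6.72. The umbrella cell list had a median of 0.37 [0.33 to 0.41] over 10 genes, 4 higher and 3 lower. This median depends on cluster 9, without which it was 1.34. Krt14 fell from 48.4 to 12.4 CPM and Krt15 from 3906 to 1925 CPM, and the basal list had a median of −0.83 over 11 genes with 3 lower. The hypoxia list had a median of −1.35 with 16 of 17 genes lower, among them Egln3, Bnip3 and Pgk1 at log2 ratios of −1.69, −1.64 and −1.63. Oxidative stress genes were higher, with a median of 0.93 and 6 of 13 genes higher, among them Hmox1, Gstm1, Nqo1 and Gclc. The G2/M list, again Ube2c and Top2a, had a median of −1.63 with both lower, and of −2.52 without cluster 9. Wfdc15b, Flrt3, Adh1, Uchl1 and Enho were among the genes most increased, at log2 ratios of 5.72, 5.39, 4.81, 4.47 and 4.24. Leaving out cluster 9 gave 5.84, 6.20, 6.37, 5.65 and 4.25 for these genes, and 6.28 for Upk3a. Ndufa4l2, Fxyd4, Ly6a, Cd53, Ptges and Cysrt1 were lowest, between −1.96 and −1.83, and without cluster 9 between −2.66 and −2.20.

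These differences were almost absent between the 625 assembloid-side urothelial-like cells of the 7-day library and the 1-day cells. The split by expression had removed the 7-day cells near bladder from this set, so medians near 0 are partly built in. Upk3a was 228 CPM in the former and 191 CPM in the latter. The list medians were 0.00 for umbrella cell genes, −0.01 for basal genes, 0.02 for hypoxia genes, 0.02 for oxidative stress genes and −0.09 for G2/M genes, and no member of these lists differed by 2-fold. With the cells between both sides included, the umbrella cell median was 0.02 and the G2/M median −0.11. Among the most different genes of this contrast were Nfkbia and Krt4, each at 0.29, Lsr at −0.32 and Tagln2 at −0.29. The SD of log2 ratios beyond counting error was 0.0953 over these genes, against 0.0526 between random sets of equal size from the 1-day cells. Mesenchymal transcripts, most of which lay in other cells, were the exception and were lower in the 7-day assembloid-side cells, with Acta2 at 148 against 371 CPM and Timp1 at 25.05 against 93.6 CPM.

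The third comparison set 7-day assembloids against adult bladder within the urothelial-like cells, which asks how close the older assembloids came to adult epithelium. Umbrella cell genes lay near their bladder levels, with Upk3a at 3971 against 5096 CPM and a list median of −0.15 [−0.19 to −0.14] over 9 genes, of which only Gsdmc2 differed by 2-fold (higher). Basal genes had a median of 0.32 over 9 genes, none changed by 2-fold, and the direction turned to −0.05 at a minimum level of 100 CPM. Hypoxia genes stayed higher, with a median of 1.30 and 10 of 15 genes higher, among them Bnip3, Egln3, Pgk1 and Vegfa at log2 ratios of 2.71, 2.69, 2.10 and 1.66. Without cluster 9 this median was 0.69, and Bnip3 and Pgk1 stood at 1.47 and 1.27. Other genes well above bladder were Ndufa4l2, Ly6a, Fxyd4, Ero1l and Ly6e, at 8.75, 5.19, 3.40, 2.53 and 1.86. Without cluster 9 these were smaller, at 6.97, 4.38, 1.72, 0.88 and 1.30, with Ero1l below a 2-fold difference. Among the lowest genes, Plaur, Pdk4, Grhl3, Hpgd and Hacd2, none reached a 2-fold decrease, and the lowest was Plaur at −0.94. No G2/M gene reached 20 CPM in either library, so the list gave no value.

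Each side of the 7-day library gave another picture of this contrast. Assembloid-side cells had medians of −0.59 for umbrella cell genes, with 3 higher and 5 lower, of 1.26 for basal genes and of 2.75 for hypoxia genes, with 18 of 18 higher. Bladder-side cells had medians of 0.01 for umbrella cell genes and 0.06 for hypoxia genes.

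Shares of urothelial-like cells with a UMI were counted after thinning every cell to 2500 UMIs. The sides of the 7-day library were chosen by expression, so shares per side describe them and are no separate evidence for the split. Upk3a was found in 98.3% [97.7 to 98.7] of bladder, 12.4% [10.7 to 14.3] of 1-day and 74.1% [72.1 to 76.0] of 7-day urothelial-like cells. Within the 7-day library it was in 14.3% of assembloid-side and 99.5% of bladder-side cells. In fibroblast-like cells, which should lack the gene, Upk3a was in 8.24%, 0.0495% and 3.58% of cells in the bladder, 1-day and 7-day libraries. The urothelial-like cells compared had median depths of 21511, 4972 and 8473 UMIs before thinning and the fibroblast-like cells 6331, 18599 and 17652, with 38, 102 and 82 urothelial-like and 209, 30 and 420 fibroblast-like cells left out as shallower. Without thinning, the Upk3a shares were 99.4%, 17.6% and 77.9% of urothelial-like and 17.5%, 0.54% and 11.4% of fibroblast-like cells.

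At this depth, Krt20 was in 13.1% of bladder, 0 of 1361 1-day and 8.34% of 7-day urothelial-like cells, and in 0.17% of assembloid-side cells. The 0 allows a share of up to 0.220% of 1-day cells with a UMI. In fibroblast-like cells Krt20 was in 0.08%, 0.099% and 0.11%, and without thinning in 46.8%, 0.21% and 21.3% of urothelial-like cells. Krt5 was in 69.5%, 59.1% and 63.8% of urothelial-like cells against 1.52%, 0.149% and 1.06% of fibroblast-like cells. Cells with both Krt5 and Upk3a made up 67.9%, 4.34% and 46.9% of urothelial-like cells, and 5.50% of the assembloid-side ones. Upk1a was in 98.5%, 63.1% and 88.3% against 7.20%, 0.396% and 3.41% of fibroblast-like cells, and Upk2 in 70.9%, 13.9% and 56.1% against 2%, 0.0495% and 0.615%. Shh was in 24.9%, 19.3% and 20.6% against 0.24%, 0.0495% and 0.168%. Krt14 was in 0.26%, 1.76% and 0.93% of urothelial-like cells, and in 2.83% of the assembloid-side ones, against 0 of 1250 bladder and 0.0495% of 1-day fibroblast-like cells. Mki67 was in 0.11%, 1.98% and 0.88% of urothelial-like cells and in 2.17% of the assembloid-side ones. Fibroblast-like cells held Mki67 in 0.40%, 2.23% and 1.57%, and in 1.83% of the assembloid-side ones. Unnamed clusters 8 and 10, with G2/M genes among their leading genes and with high Acta2 and Col1a1, are outside this class. They held 721 and 600 cells at 1 day and 294 and 371 at 7 days. Mki67 and G2/M shares of fibroblast-like cells may therefore leave out many dividing stromal cells. Cells with at least 3 G2/M genes made up 0 of 2650 bladder urothelial-like cells, which allows up to 0.113%, with 2.42% at 1 day, 0.69% at 7 days and 2.33% among assembloid-side cells, against 0.16%, 4.75% and 2.29% of fibroblast-like cells and 2.92% of the assembloid-side ones. Without thinning these G2/M shares were 0.149%, 3.21% and 1.08% of urothelial-like cells.

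In fibroblast-like cells, the comparison of 1-day assembloids with adult bladder asks how stromal cells differ in culture. Almost all bladder cells of this class lay in clusters 2, 22 and 24 and the 1-day cells in clusters 1, 4 and 23. The ratios thus compare different clusters, and different cell types under the same name are not excluded. Cluster 1, with 1477 of the 1-day cells, was named on 4 counted fibroblast markers. Unnamed clusters 3, 6, 8 and 10, which also had high Acta2 and Col1a1, are left out. Within these limits, adult fibroblast genes were low and contractile genes high at 1 day. Dcn (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143), the small proteoglycan decorin, fell from 21476 to 831 CPM, a log2 ratio of −4.69. Lum fell from 2319 to 85.4 CPM, elastin (Eln) from 737 to 33.8 CPM and Col6a1 from 1623 to 98.9 CPM. The fibrillar matrix list had a median of −1.32 [−1.32 to −1.29] over 16 genes, 9 lower and 0 higher, at the 0.07 percentile of random lists. The contractile list had a median of 3.85 with 13 of 14 genes higher and 1 lower. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), a marker of activated fibroblasts and of muscle, rose from 104 to 10071 CPM, Actg2 from 11 to 2205 CPM, Cnn1 from 8.8 to 643 CPM and Tagln from 109 to 6056 CPM. The tissue inhibitor Timp1 rose from 76.7 to 5356 CPM within a remodelling list with 7 of 13 genes higher and 3 lower, among the latter Mmp2.

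Signalling and stress genes of fibroblast-like cells also differed between 1-day assembloids and bladder. All 15 immediate early genes were lower, with a median of −4.11, among them Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) from 2801 to 56.2 CPM and Hspa1a from 3933 to 12.7 CPM. Dissociation can induce these genes, so here and in the comparisons below their levels cannot be told apart from effects of handling. Hedgehog targets were lower, with Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974) at 2 against 267 UMIs, a log2 ratio of −8.92 [−12.29 to −7.37], Hhip at a log2 ratio of −8.02, and Ptch1 at 5.2 against 108 CPM, and the list median was −4.37 over 5 genes. The Wnt list had a median of −2.45 with 8 of 10 genes lower, among them Lgr5 and Sfrp2 (121 to 2.1 CPM). The BMP list had a median of −2.49 with 9 of 11 genes lower, among them Bmp2 and Bmp5, while the antagonist Grem1 rose from 1 UMI to 35.2 CPM, a log2 ratio of 7.65 [5.75 to 13.54]. Cholesterol synthesis genes had a median of 2.09 with 9 of 11 higher, among them Fdps (14.6 to 143 CPM). The hypoxia list had a median of 1.27 with 7 of 14 genes higher, among them Eno1 (66.2 to 610.1 CPM), and Ndrg1 lower. The G2/M genes were higher, 5 of 5 with a median of 3.41, and 2 of 4 S phase genes, without the dividing cells of unnamed clusters 8 and 10. All 5 antigen presentation genes were lower, among them H2-D1 (524 to 57.0 CPM). In the cytokine list 4 of 9 genes were higher and 4 lower, and Cxcl10 fell from 33.4 CPM to 0 UMIs, at least 431-fold against the floor of 3 counts. Lists with few differences were interferon response (median −0.34, 1 of 5 genes higher and 1 lower) and oxidative stress (median 0.19 over 11 genes), and oxidative phosphorylation had a median of 0.87 with 6 of 14 genes higher. Spp1 rose from 3 UMIs to 337 CPM, a log2 ratio of 9.69 [8.36 to 12.19], Ankrd1 from 2 UMIs to 180 CPM, a log2 ratio of 9.27 [7.73 to 12.63], and the activin subunit Inhba from 7.71 to 694 CPM. The adult fibroblast genes Clec3b and Cd34 fell from 2433 to 0.21 and from 708 to 1.03 CPM, and Car3 fell to 2 UMIs, a log2 ratio of −12.68 [−16.04 to −11.14].

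Between 1 and 7 days, the fibroblast-like cells differed in their clusters as well as in their levels. Cluster 1 went from 1477 to 220 cells, cluster 4 from 473 to 905 and cluster 23 from 100 to 270, so values of the class include this change of mix, also among assembloid-side cells. Bmp4 (ENSMUSG00000021835, chromosome 14, 46383520 to 46390669), a stromal growth factor, rose from 40.3 to 213 CPM, and to 207 CPM in the 1386 assembloid-side fibroblast-like cells, a log2 ratio of 2.36 [2.28 to 2.44]. Within clusters 1, 4 and 23 taken alone, a split chosen after the results were seen, the assembloid-side ratios of Bmp4 were smaller, at 1.15, 0.99 and 1.02, those of Lum were 1.36, 1.05 and 1.09, and those of Dcn were 0.43, 0.69 and 1.12, below 2-fold in clusters 1 and 4. Lum rose from 85.4 to 547 CPM (422 CPM in assembloid-side cells) and Dcn from 831 to 3851 CPM (2542 CPM). The fibrillar matrix list had a median of 0.29 [0.28 to 0.29] over 16 genes with 6 higher and 0 lower, and of 0.21 with 2 higher among assembloid-side cells. The Wnt list had a median of 1.30 with 5 of 8 genes higher, and of 1.03 with 4 of 7 higher among assembloid-side cells, where Dkk2, Wnt2, Nkd1 and Sfrp1 stood at log2 ratios of 1.85, 1.44, 1.42 and 1.03. No difference in Dkk2 was detected within any of the 3 clusters (−0.10, −0.39 and 0.12, with 0 inside each interval). Dkk2 and Bmp4 are leading genes of cluster 23, whose share was larger at 7 days. The clusters were formed from expression in cells of both ages. Ratios within them therefore cannot separate a change of mix from a change of expression. Wnt2 stood at −0.066, 0.55 and 1.15 within these clusters. Nkd1 stood at 1.09, 1.01 and 0.55 within them, and Sfrp1 at 0.84, 0.56 and 0.70, below 2-fold in each. The stricter cell filter took the first of these Wnt medians to −0.000301. The BMP list had medians of 0.92 and 0.89, with Id2 higher in both. The chemokine Ccl2 rose from 81.3 to 471 CPM in assembloid-side cells, where 3 of 5 cytokine genes were higher, and its ratios within the 3 clusters were 1.26, 1.52 and 1.36.

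Immediate early genes were higher at 7 days, 11 of 15 with a median of 1.43, and 3 of 14 with a median of 0.79 among assembloid-side cells, with Fos from 56.2 to 185 CPM. The contractile list had a median of −0.52 with 1 of 13 genes lower, Cnn1, and of −0.43 among assembloid-side cells. Timp1 fell, at a log2 ratio of −1.50 (−1.40 in assembloid-side cells), and so did Tnfsf15, Prss23, Tes, Ncam1 and Inhba, at −1.81, −1.51, −1.45, −1.45 and −1.41. Within clusters 1, 4 and 23 the assembloid-side ratios were smaller, at −0.91, −1.28 and −0.77 for Timp1 and at −0.53, −1.11 and −0.99 for Inhba. In assembloid-side cells Ifitm1 and Ly6a were higher, at 3.53 and 2.25. The 30 bladder genes under 2 CPM in the 1-day library were also 5.02 times as high in these cells as in 1-day fibroblast-like cells (120 against 23.9 CPM), and Upk3a, a urothelial gene outside that set, stood at 18.5 against 0.28 CPM. The 30 genes were chosen for low levels in the 1-day library, which favours a higher level at 7 days. The largest increases in the whole library, Clec3b, Pi16 and Fmo2 at 9.45, 4.93 and 4.84, were smaller among assembloid-side cells, where Clec3b stood at 4.22 against 0.21 CPM, a log2 ratio of 4.27, Pi16 at 1.43 and Fmo2 at 1.83, all at low levels. The G2/M list had a median of −0.38 over 5 genes with 1 lower, and the hypoxia list a median of −0.08 over 13 genes. The dividing cells of unnamed clusters 8 and 10 are outside this class, so the G2/M median does not describe all stromal cells.

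Against adult bladder, 7-day fibroblast-like cells stayed apart. The fibrillar matrix list had a median of −0.93 [−0.94 to −0.92] with 7 of 16 genes lower and 0 higher, among them Eln, Col6a1, Col6a2 and Dcn at log2 ratios of −2.98, −2.64, −2.63 and −2.48. Among assembloid-side cells the median was −1.02 with 8 lower, and these genes stood at −3.54, −3.31, −3.30 and −3.08. For the whole library the median shrank to −0.50 with per-cell CPM averaged and to −0.59 with thinned cells. The contractile list had a median of 3.46 (3.55 in assembloid-side cells, whose medians are in parentheses from here) with 11 of 14 genes higher, and Actg2, Acta2 and Tagln stood at 7.14, 5.89 and 5.05. Immediate early genes were lower, 14 of 15 with a median of −2.74 (−3.41). Cholesterol synthesis genes were higher, 9 of 11 with a median of 2.66 (2.75), and so were 8 of 14 hypoxia genes. Hedgehog genes were lower, 4 of 5 with a median of −2.85 (−3.78), and the Wnt, BMP and antigen presentation lists had medians of −0.80, −1.01 and −1.33 (−0.88, −1.12 and −1.52). Asns and Inhba were higher, at 6.08 and 5.07, and Sfrp4, Scara5, Clec3b, Itgbl1, Pi16 and Angptl7 lower, between −4.29 and −3.92. In assembloid-side cells Asns and Inhba stood at 6.18 and 5.17, and the lower genes were much further from bladder, with Clec3b, Angptl7 and Pi16 at −9.17, −7.57 and −7.43 and Itgbl1, Sfrp4 and Scara5 at −7.13, −6.20 and −6.18. In the bladder-side cells, by contrast, the matrix list had a median of −0.04 against bladder and the contractile list 0.45, with Acta2 at 294 against 104 CPM.

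**Figure D4:**
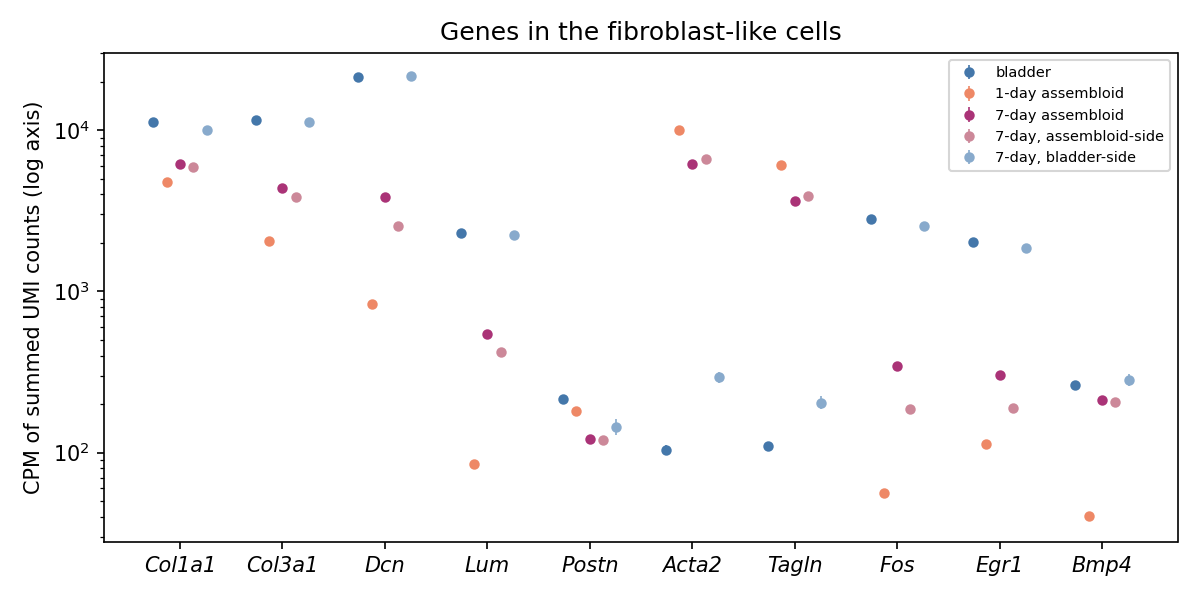
CPM of 10 genes in fibroblast-like cells (log y axis) in bladder, 1-day and 7-day libraries and in both sides of the 7-day library, with exact Poisson 95% intervals, genes at 0 counts not drawn. Dcn stood at 21476 CPM in bladder and 831 CPM at 1 day, and Bmp4 at 40.3 CPM at 1 day and 213 CPM at 7 days.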

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

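The tests reported in this part were chosen after the results they bear on were seen, except those of free RNA and of cells without either sex-linked transcript, whose outcomes were written down before.

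Human cells were found in the assembloid libraries, outside the mouse measurements of the comparisons. At the same limits as mouse cells, 114 human cells were kept at 1 day and 73 at 7 days, with a median of 10969 and 16081 UMIs, and 0 in bladder, where human barcodes held at most 1 UMI. They stood out because the samples are labelled as mouse and the bladder library, processed on the same combined gene set, held none. Of the marker lists, the endothelial one had 3 of 11 genes at 1 day and 4 of 11 at 7 days in over 50% of the human cells, and the urothelial one 3 of 19 at both ages, while summed levels were higher for urothelial (1169 and 1094 CPM) than for endothelial markers (889 and 920 CPM). The median endothelial marker was in 13.2% and 16.4% of the human cells at 1 and 7 days. The median urothelial marker was in 0% and 1.37%. CDH5 was in 72.8% and 86.3% of the human cells, MKI67 in 64.0% and 64.4% and VIM in 99.1% and 100%. List medians between the ages lay near 0, with 0.09 for G2/M genes and −0.47 for cholesterol synthesis genes, of which 2 of 13 were lower. Of barcodes found in both assembloid libraries (114), 78 were human cells at 1 day, and their 7-day counterparts held a median of 0.229% of the UMIs. The origin of these cells is not given in the sources used here and was not tested.

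In the 7-day library, 3590 cells had bladder cells as their nearest cells, with between 0.423 and 0.687 7-day cells for each bladder cell over 13 clusters and median UMIs at 0.410 to 0.535 of those in bladder, while against 1-day cells these ratios ran from 0.0792 to 2.70 and from 0.759 to 1.58. Even ratios were not particular to the bladder side. Unnamed clusters 3, 6, 8 and 10 and urothelial-like clusters 7 and 9 lay between 0.408 and 0.618 7-day cells for each 1-day cell. Their median UMIs were 1.29 to 1.57 times those at 1 day. Reads moved between libraries under the same barcodes are argued against, since 0.5014% of the bladder-side barcodes (18 of 3590) were in the bladder list. A separate bladder capture merged with the 7-day data was not decided by free RNA. The 30 assembloid genes under 2 CPM in the bladder library stood at 2.713 times [2.53 to 2.91] their bladder level in the bladder-side cells (67.9 against 25.01 CPM summed over named classes). This pooled ratio met the mark set against a separate capture, a lower limit over 2. It was carried by urothelial-like (11.03) and smooth muscle-like cells (4.28). The ratio was below 2 in 4 of 6 classes, endothelial-like (1.87 [1.60 to 2.18]), fibroblast-like (1.70), pericyte-like (1.09) and glia-like cells (0.623), and in 3 the upper limit was under 2. The genes were also chosen for low levels in this bladder library, so another bladder sample could read higher. Adult bladder cells present in the 7-day suspension may explain the pattern. They cannot be told apart from a separate bladder capture, nor from assembloid cells that took on adult profiles over 7 days, the biological reading the design names. The same 2.713 splits by class. Xist was in 0.3774% (upper limit 1.36%) of bladder-side mesenchymal cells against 0.193% in assembloid-side ones, or 8.63% with the unnamed clusters added. This speaks against conversion of unnamed cells that kept Xist, but not of cells without it or that lost it. The bladder-side to bladder ratios of the 13 clusters spanned 2.011-fold, short of the spread above 3-fold set as the mark of such a conversion. The opposite mark required 10% of the bladder-side cells in a class without 1-day cells. Lymphocytes, the only such class, were 0.251% of them. This mark could not have been met, since lymphocytes were only 0.545% of the bladder library itself, so it decides nothing.

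Xist, the transcript of the inactive X chromosome, was in 14.3% [12.8 to 15.9] of 1-day fibroblast-like mouse cells at equal depth and in 0.17% of 7-day ones. Bladder-side cells in the class are argued against as the cause, since the assembloid-side cells alone had 0.2191%. Cells with a Y-linked transcript made up 29% [26.6 to 31.5] of assembloid-side cells and 19.0% [17.3 to 20.7] of 1-day cells, which is consistent with another mix of donor sexes in the pools, and such a mix would confound the ages. Lower expression of Xist in the same donors stays open, since cells with neither transcript rose by 3.752 points where Xist fell by 14.0 points. Xist was also lower at 7 days in endothelial-like cells (13.7% to 0.314%) and unnamed cluster 8 (14.5% to 0.68%), while unnamed clusters 3, 6 and 10 kept it in 15.2%, 23.1% and 23.2% of 7-day cells (16.1%, 25.2% and 23.3% at 1 day), and no other biological explanation was tested.

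The assembloid-side urothelial-like cells of the 7-day library lay close to the 1-day cells, with an SD of log2 ratios of 0.0953 beyond counting error. Choice of cells by their neighbours is not excluded as the cause. Fibroblast-like cells chosen in the same way had an SD of 0.3808, so the choice does not force closeness in every class. In the urothelial-like class, however, it sets 1472 7-day cells near bladder apart, so cells with adult profiles are removed by construction. Too few counts are argued against as well, since counting error alone gave an SD of 0.06013. The closeness was not particular to the epithelium, since the 7-day cells of unnamed clusters 3, 6 and 10 had SDs of 0.0611, 0.0625 and 0.0694 against 1-day cells (0.302 in cluster 8), and smooth muscle-like cells 0.157 where random sets of their 1-day cells gave 0.142. Its cause stays open, with 1 library per age. A different donor mix is not excluded, but sex-linked transcripts gave no clear sign of one in the urothelial-like cells. Xist was in 0.588% of 1-day and 0.167% of assembloid-side cells and a Y-linked transcript in 29.4% and 32.3%, with overlapping intervals.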

How the results depend on the processing

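The tests without cluster 9, without bladder-side cells and with 1-day cells of Y-linked transcripts were chosen after the results were seen; the others were planned. Among planned values of the shares and of the umbrella cell, G2/M and matrix medians, 68 stayed within the counting interval, 36 moved beyond it and none turned direction. For the other planned values the numbers were 878, 540 and 12 reversed, and for the other added ones 104, 102 and 3. Of the added values of the shares and of these 3 medians, 4 stayed, 12 moved and none turned. Resolution 0.5 and Scrublet calls kept left all shares and these 3 medians within their intervals, and no minimum level, which was run for medians only, left these medians within theirs. Unless stated, the cause was not tested. Below, medians of fibroblast-like matrix genes follow the order 7-day over 1-day, 7-day over bladder and 1-day over bladder (main values 0.29, −0.93 and −1.32), as do umbrella cell medians (0.37, −0.15 and −0.60). The G2/M medians are 7-day over 1-day and 1-day over bladder (−1.63 and 5.10).

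The looser filter gave a bladder urothelial-like share of 38.3% and matrix medians of 0.32 and −0.88 in the first 2 comparisons. The stricter filter gave a 7-day share of 27.8%, matrix medians of 0.20, −1.06 and −1.21, umbrella cell medians of −0.14 and −0.55 against bladder, a 1-day G2/M median of 5.66, and a fibroblast-like Wnt median (7-day over 1-day) of −0.000301 in place of 1.30. Resolution 2 gave matrix medians of 0.16, −0.92 and −1.13, and the class by most marker UMIs 0.35, −0.89 and −1.17.

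Per-cell CPM averaged gave matrix medians of 0.51, −0.50 and −1.07, umbrella cell medians of 0.42, −0.21 and −0.69, a 1-day G2/M median of 5.96, and turned the fibroblast-like cholesterol median (7-day over 1-day) from 0.33 to −0.15. Median-of-ratios scaling gave matrix medians of 0.30, −1.06 and −1.48 and umbrella cell medians of 0.54 (7-day over 1-day) and −0.77 (1-day over bladder), by the shift it applies to every gene. Thinned cells gave matrix medians of 0.47, −0.59 and −1.17, umbrella cell medians of 0.50, −0.20 and −0.75 and a 1-day G2/M median of 5.67.

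A minimum of 100 CPM, which measures fewer genes, gave a matrix median of 0.21 (7-day over 1-day) and turned 7 urothelial-like medians: tight junction −0.14 and BMP −0.31 (7-day over 1-day), basal −0.047 and remodelling −0.94 (7-day over bladder), and tight junction 0.14, BMP 0.082 and remodelling −3.66 (1-day over bladder). It left no G2/M gene, so that list has no value there. With no minimum, which adds genes of few counts, cytokine medians turned to −0.26 (7-day over 1-day) and 2.83 (1-day over bladder), and BMP to 0.45 (1-day over bladder). G2/M genes gave no value for 7-day over bladder.

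With cluster 9 left unnamed, which removes 702 and 310 cells, the urothelial-like share was 9.21% at 1 day and 22.2% at 7 days, the umbrella cell medians 1.34 (7-day over 1-day) and −1.57 (1-day over bladder), and the G2/M medians −2.52 and 6.03. Without bladder-side cells, which removes 3590 cells, the 7-day share was 14.2%, the umbrella cell medians 0.017 and −0.57, the G2/M median −0.11 and the matrix medians 0.21 and −1.02, and urothelial-like medians (7-day over 1-day) turned to −0.031 for tight junction, 0.000515 for hypoxia and −0.14 for cytokine genes. Among other changes of sign, counted as moved, hedgehog went from −0.55 to 0.017 and interferon from −0.44 to 0.062 in that comparison. Hedgehog against bladder went from −0.33 to 0.78. With the 1171 1-day fibroblast-like cells that had a Y-linked transcript and no Xist, matrix medians were 0.28 and −1.31 (7-day over 1-day and 1-day over bladder).

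No paired analysis was possible because each group has 1 library and the replicate numbers are names only. Depth limits rare transcripts, and 1575 cells of the 7-day library were below 2500 UMIs and left out of the thinned shares.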

Other observations

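Every value in this part was looked at after the data were seen, apart from the lists of the other classes, which were planned.

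Endothelial-like cells of 1-day assembloids lay in clusters 15, 21 and 31 and those of bladder in clusters 16, 17, 18 and 21, with a single 1-day cell in cluster 18, so the class values compare mostly different clusters. All 15 immediate early genes were lower, with a median log2 ratio of −3.83, 11 of 11 G2/M genes were higher with a median of 2.28, and 11 of 15 hypoxia genes were higher with a median of 1.52. Interferon genes had a median of −3.44 with 8 of 12 lower. Apln, the ligand apelin of sprouting vessels, was at 985 against 0.56 CPM, and Pgf at 1367 against 24.4 CPM, while the lymphatic chemokine Ccl21a fell to 3 UMIs, a log2 ratio of −10.69 [−13.19 to −9.37]. From 1 to 7 days, the 327 assembloid-side endothelial-like cells had more Gpihbp1 (47.1 to 290 CPM), Sparcl1 and Dll4, at log2 ratios of 2.62, 2.05 and 1.54, and less Phgdh, Hmox1 and Asns, at −2.50, −1.86 and −1.56. Smooth muscle-like cells had fewer contractile transcripts at 1 day than in bladder, with 8 of 15 genes lower and a median of −1.94, and 8 of 8 G2/M genes higher. All 270 of these 1-day cells lay in cluster 19 and the 618 bladder cells in clusters 11 and 28, so a different cell type under the same name is not excluded. Cluster 19 shares its leading genes Sprr2k and Crabp1 with unnamed cluster 3, and was shallower at 1 day, with a median of 5352.5 against 21261.5 UMIs. Smooth muscle was the candidate class of cluster 3, so this contrast may rest on part of a larger population.

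Glia-like cells fell into cluster 12 in assembloids (687 cells at 1 day and 60 at 7 days) and cluster 20 in bladder (287 cells, with 133 at 7 days). Unnamed clusters 3, 6, 8 and 10 held 902, 764, 721 and 600 cells at 1 day and 518, 460, 294 and 371 at 7 days. All of them had high Acta2 at 1 day (9831, 7953, 9417 and 7052 CPM) and Col1a1 (2398, 3170, 4617 and 2356 CPM). Cluster 3 had Crabp1 at 267 CPM and cluster 6 Spp1 at 3095 CPM, and clusters 8 and 10 had Mki67 at 193 and 205 CPM against 3.7 and 4.7 CPM in the others. The small cluster 34, with 6, 18 and 7 cells, had the neuronal genes Prph, Stmn3 and Pcsk1n among its leading genes.

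The 30 bladder genes under 2 CPM in the 1-day library were higher in the assembloid-side 7-day cells than in the same classes at 1 day, by 3.08 times over all named classes (157 against 51.1 CPM). By class the ratios were 1.44 in urothelial-like, 2.51 in endothelial-like, 4.77 in glia-like, 5.02 in fibroblast-like and 34.8 [19.6 to 68.1] in smooth muscle-like cells, the last against only 12 UMIs at 1 day. The genes were chosen for low levels in this 1-day library, so another assembloid library could read higher by that choice. Free RNA from the bladder-side cells was not told apart from expression.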
